A study of Mus musculus with 59 samples.

How the data were processed

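RNA from the mouse brain samples was measured on Affymetrix Mouse 430 2.0 arrays. The deposited values are a linear signal intensity per probe set, and the submitters' processing notes name GCOS. The signal algorithm, a target value and any scaling between arrays are not given in the sources used here. The authors' intensity values were not brought to a common level: the 2% trimmed mean ran from 197.6 to 419.4 over the 59 arrays. All 59 arrays were used, and 0 of 1711 pairs were identical. As signs of RNA quality, the ratio of 3-prime to 5-prime control signals lay between 1.03 and 1.39 for Actb and between 0.724 and 0.822 for Gapdh, and arrays of a group correlated at 0.972 to 0.991 on the log2 scale. The number of arrays per group, 3 or 4, sets the precision.

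Each array was scaled to a 2% trimmed mean of 500, values under a floor of 32 were set to 32, and log2 was taken. Between 18.2% and 38.0% of probe sets lay at the floor, so a change of a gene at the floor in 1 group is a bound. Of 45101 probe sets, 34958 carried 1 gene symbol in the probe annotation, 932 several and 9211 none; the Entrez number of 34754 matched the mouse gene table (assembly GRCm38.p6, used for names only). The 18194 genes had 1 probe set each in the tests, chosen by mean signal without regard to group, and 9012 genes had more than 1. A gene was tested where its scaled signal was at least 100 in at least 3 arrays (4 at P84) of the arrays compared.

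Groups were compared with limma 3.58.1 in R 4.3.3 (with the data.table package, version 1.17.8): a linear model with 1 term per group over all arrays of an age and tissue, empirical Bayes moderation with an intensity trend, and Benjamini-Hochberg adjustment over the genes tested, with a threshold of 0.05. There were 20 comparisons within an age and tissue and 2 of a VPA effect between sets. Intervals are 95% and fold thresholds 1.5 and 2. Gene lists, 38 in all with 640 members of which 577 matched a probe set, were tested with camera at a preset inter-gene correlation of 0.01 and adjusted over the lists of a comparison; lists with under 3 tested members were left out. Members were also adjusted over the list alone. Of 831 list tests 147 passed, and 0 passed with an estimated correlation. List scores are the mean log2 signal of the members minus the MC mean, compared by exact two-sided permutation tests. The similarity of VPA and VPM was set beside 100 simulated pairs of unchanged groups sharing their controls. Figures were drawn with Python 3.11.15, matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3.

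Genes are named by a rule: up to 12 with the largest rise and 12 with the largest fall among genes with an adjusted p under 0.05, groups that do not overlap, a mean scaled signal of at least 200 in the higher group and 1 symbol; where fewer than 10 genes passed, also the 5 with the smallest p, stated not to pass; and up to 4 members per list with the smallest adjusted p. Predicted genes and clone names were not named, and some genes that the rule gives are not used here. Genes outside the rule, such as Alas2, Hba-a2, Dcx and Tfrc where it is followed elsewhere, were chosen after their values were seen.

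The procedure was tested on simulated data with 100 genes changed by 0.5 and 100 by 1 on the log2 scale at the spread of the real arrays. For VPA at E14.5 (11074 genes) 60% and 96% were recovered with 6 false calls of 162, in the E18.5 forebrain (11515 genes) 72% and 92%, in adult hippocampus (13479 genes) 40% and 86%, in adult cortex (13621 genes) 49% and 86%, and at P84 (13051 genes) 67% and 90%. Of 200 simulated unchanged lists per comparison, 0 were called, but real arrays gave more: with the P84 arrays split in other ways, a median of 3 lists and up to 9 were called at the preset correlation.

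The lists, the tests, the rule and the first set of alternatives were fixed before the data were examined. These alternatives were quantile normalization, the values as deposited, log2(signal + 32) in place of the floor, no filter and a filter at 200, moderation without a trend, every probe set in place of 1 per gene, the mean over the probe sets of a gene for lists, the replicate number as a block, only the arrays of the 2 groups compared, the estimated correlation, and leaving out each array in turn. Inferred sex as a covariate for embryos and the restriction to genes changed 2-fold or more at E14.5 were added after the data had been seen. Other splits of the samples were counted, all 10 for 3 against 3, all 35 for 4 against 4 and 100 drawn otherwise.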

Results

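The series measured messenger RNA in brain tissue of C57BL/6 mice on 59 Affymetrix Mouse 430 2.0 arrays. Pregnant dams were dosed by mouth on E12.5, E13.5 and E14.5 with the vehicle methylcellulose (MC, 0.5%), with valproic acid (VPA, an anti-epileptic drug, 300 mg/kg) or with valpromide (VPM, the amide of VPA, 300 mg/kg). The telencephalon was taken at E14.5, 3 h after the last dose, and the hippocampus and the forebrain at E18.5, from MC, VPA and VPM groups of 3 arrays each. Adult hippocampus and cortex came from offspring aged 12 to 13 weeks in 4 groups of 3 arrays: MC, VPA, and both again with a running wheel (MC+RW, VPA+RW). A further set held the hippocampus at P84 from MC and VPA offspring, with 4 arrays per group. The arrays fell into 19 groups, and their number limits the precision of every value. Signals below are scaled to a trimmed mean of 500 per array and given as mean ± SD. Of the 27 embryonic arrays, 12 showed the female pattern (high Xist), and of the 32 adult arrays 0 did. Litters are not named in the labels, so whether the arrays of a group came from separate dams could not be checked.

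The first comparison asked what VPA did to the telencephalon while the dams were being dosed. Kmt5b, which encodes a histone H4 lysine methyltransferase, fell from 1902 ± 16.2 in MC to 394 ± 35.4 in VPA (n = 3 each), a log2 change of -2.27 with a limma adjusted p of 9.28e-09. The inducible heat shock genes Hspa1a and Hspa1b rose from 35.1 ± 10.5 to 274 ± 12.1 and from 68.4 ± 14.3 to 412 ± 83.5, log2 changes of 2.91 and 2.59. H2-Ab1, a class II histocompatibility chain, stood at 5.63 ± 0.949 in MC, below the floor of 32, and at 318 ± 96.3 in VPA, at least 9.62-fold higher. The proneural gene Neurog1 fell from 499 ± 45.0 to 116 ± 21.4, a log2 change of -2.12 with an adjusted p of 1.13e-06. Further large rises included those of Rwdd2a (2.78), the elongation factor gene Ell2 (2.75), Hes7 (2.61), Rasd2 (2.59), Ier3 (2.48), the stress-induced sestrin gene Sesn2 (2.48), Tmem159 (2.46) and the transcription factor gene Mitf (2.45). Further large falls were those of Dis3l (-2.42), Nsmaf (-2.27), Taf9b (-2.22), the mitochondrial carrier gene Slc25a26 (-2.14), Nxph2 (-2.02), Zfp618 (-2.02), Ttc32 (-2.00), Atxn7l2 (-1.98), Masp1 (-1.98) and the sialyltransferase gene St6gal2 (-1.94). In each of these genes the 3 VPA arrays did not overlap the 3 MC arrays, as the naming rule required. For Hspa1a, Ell2, Hes7 and Mitf 2 of the MC arrays lay under the floor, so their log2 changes are lower bounds.

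Of 11074 genes tested, 5961 (53.8%) changed with VPA at E14.5, 2996 upward and 2965 downward. The change was 1.5-fold or more in 2271 of them, and 2-fold or more upward in 387 and downward in 309. The unadjusted p was under 0.05 in 6499 genes, where chance alone gives 554. The groups did not overlap in 60.2% of the genes tested, against 10% by chance for 3 arrays against 3. Among called genes with other tested probe sets, 93.5% of the other 4962 probe sets changed in the same direction, and in 28 genes another called probe set went the opposite way.

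**Figure D1:**
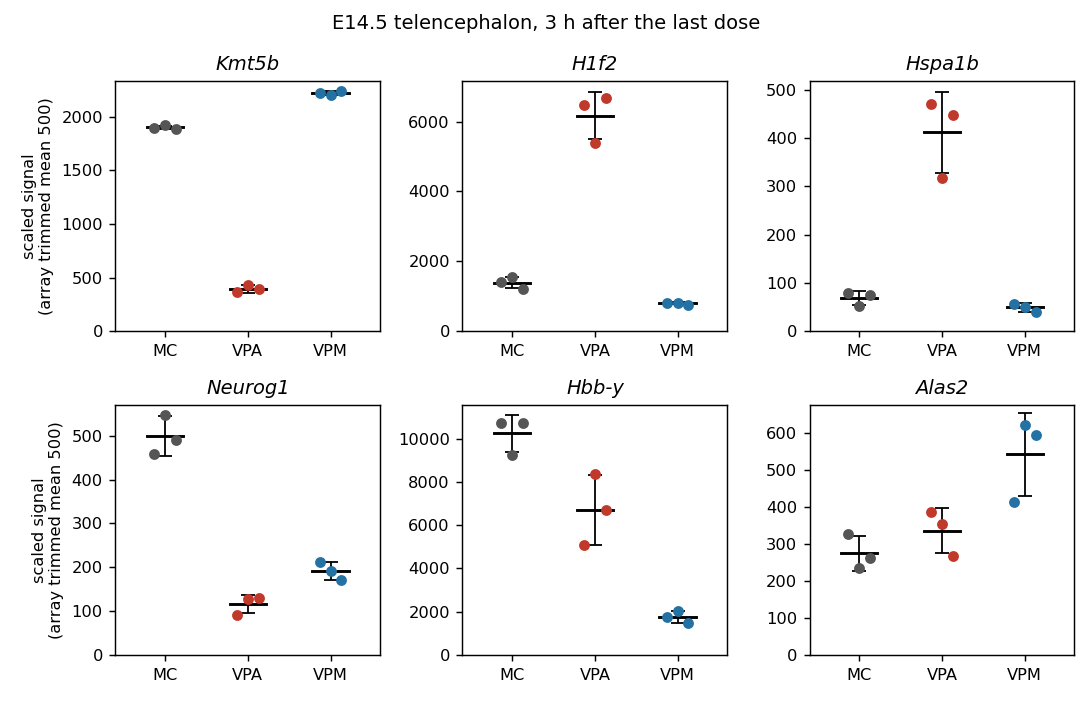
Scaled signal (linear axis, array trimmed mean 500) of 6 genes in each array of the E14.5 telencephalon by dosing group, with group means. Kmt5b fell from 1902 to 394 with VPA, H1f2 rose to 6175, and Hbb-y fell from 10244 to 1751 with VPM.

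Gene lists fixed before the data were examined showed which groups of genes moved. Among 14 measured genes known to respond to inhibitors of histone deacetylases, 9 rose, 1 fell and 4 did not pass. They included the linker histone gene H1f2 (2.15), Hspa1a, Hspa1b and the cell cycle inhibitor gene Cdkn1a (1.46), and the list's median log2 change was 0.77 (camera adjusted p = 0.00753; adjusted p = 0.244 with an estimated correlation). Intermediate progenitor genes were lower: 11 of 14 fell and 0 rose, or 12 fell adjusted over the list alone, with a median of -0.63 (adjusted p = 0.000546; adjusted p = 0.329 with an estimated correlation). Sstr2 (-1.06), Neurog1, Eomes (-0.92) and Neurog2 (-0.83) had the smallest adjusted p of that list. Cell cycle genes were lower as a group, with 24 of 32 fallen, among them Plk1 (-0.80), Ccna2 (-0.57), Mki67 (-0.76) and Ccnb2 (-0.80), while 3 rose, Ccne1 (0.71) among them. Their median was -0.41 (adjusted p = 0.000505; adjusted p = 0.487 with an estimated correlation). Of 20 radial glia and neural stem cell genes, 12 fell, 1 rose and 7 did not pass, with Gli3 (-0.61), Sox9 (-0.70), Hes1 (-0.78) and Id4 (-0.42) in front and a median of -0.31 (adjusted p = 0.0115; adjusted p = 0.244 with an estimated correlation). Immature neuron genes fell in 11 of 19 and rose in 0, with Nhlh2 (-1.07), Tbr1 (-1.38), Nhlh1 (-0.88) and Bcl11b (-0.40) first and a median of -0.16 (adjusted p = 0.017; adjusted p = 0.392 with an estimated correlation). Clock genes went the other way: 9 of 13 rose and 1 fell, led by Cry2 (0.83), Cry1 (1.08), Dbp (1.18) and Nr1d1 (1.30), with a median of 0.61 (adjusted p = 0.0115; adjusted p = 0.244 with an estimated correlation). The p53 target list did not pass (adjusted p = 0.0555), although 8 of 12 members rose and 2 fell, Bbc3 (1.71), Sesn2 and Aen (0.69) among the risers. Histone deacetylase genes changed both ways, with Hdac1 (0.60), Hdac6 (0.53) and Hdac5 (0.51) up and Hdac7 (-0.93) and Hdac9 (-1.10) down (list adjusted p = 0.5). In all, 6 of 38 lists passed with the preset correlation and 0 with an estimated one. Adjusted over the list alone, the numbers of risers and fallers were those given except where stated.

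VPM was compared with MC at the same age to ask whether the amide gave a response of its own. The embryonic globin genes Hbb-y and Hba-x had the largest falls: Hbb-y from 10244 ± 848 to 1751 ± 280 (log2 change -2.56, adjusted p 9.5e-06, n = 3 each by limma) and Hba-x from 1404 ± 89.8 to 317 ± 57.8 (-2.16). Alas2, the heme synthesis gene of red cells, rose from 275 ± 47.7 to 544 ± 112 (0.97, adjusted p 0.00773), and Hba-a2, a later globin gene, did not pass (-0.23, adjusted p 0.5). Neurog1 fell from 499 ± 45.0 to 191 ± 21.1 (-1.39), and so did the chromatin gene Hmga2 (-1.34) and the Notch effector gene Hes1 (-0.92). Other large falls were in Pawr, Tcf7l1 (-0.95), Ppp1r14a (-0.94), Dct (-0.94), Nfatc4 (-0.83), Dmrt3 (-0.83) and Shisa2 (-0.82). Among genes with a mean scaled signal of at least 200 in the higher group, the largest rise was that of Scrg1, from 113 ± 27.5 to 306 ± 56.2 (1.45, adjusted p 0.00339). Rises followed in Pdgfra (the growth factor receptor of oligodendrocyte precursors, 1.24), the noncoding Meg3 (1.23), the glutamate receptor gene Grm3 (1.22), Dync1i1 (1.18), Marchf4 (1.16), Ccbe1 (1.15), Kcnip2 (1.15), Ptprr (1.14), Stum (1.12), Neto1 (1.09) and the thyroid hormone transporter gene Slco1c1 (1.06). Dct, Ptprr, Stum and Dmrt3 lost their call without single arrays. Without VPM replicate 3 the adjusted p was 0.0806 for Dct, 0.0935 for Ptprr and 0.0662 for Stum, and without MC replicate 2 it was 0.0632 for Dmrt3. Without a filter these genes lost their call too, as did Pdgfra (limma adjusted p 0.0776), Meg3 (0.0945), Ccbe1 (0.087) and Ppp1r14a (0.0571).

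VPM changed 1266 of 11074 genes (11.4%), 625 upward and 641 downward, at 2-fold or more in 34 and 8. The unadjusted p was under 0.05 in 3009 genes, and the groups did not overlap in 32.6% against 10% by chance. The count was 531 without VPM replicate 3, 768 without MC replicate 2 and 738 without MC replicate 3. With the values as deposited it was 425, of which 166 were higher and 259 lower, 39.1% higher against 49.4%. VPM replicate 3 also carried a choroid plexus signal: its scaled Ttr was 19330, against at most 45.3 in the MC arrays.

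All 32 measured cell cycle genes were lower with VPM, 28 fell (31 adjusted over the list alone), and the median was -0.43 (adjusted p = 9.63e-19; adjusted p = 0.152 with an estimated correlation). The replication genes Mcm4 (-0.46) and Mcm5 (-0.54) and the mitotic genes Cenpf (-0.48) and Cdca8 (-0.48) had the smallest adjusted p. Of 14 intermediate progenitor genes 9 fell (12 adjusted over the list alone), with Neurog1, Eomes (-0.56), Neurog2 (-0.60) and Rhbdl3 (-0.65) first and a median of -0.49 (adjusted p = 3.23e-08; adjusted p = 0.152 with an estimated correlation). Radial glia genes fell in 12 of 20 (13 adjusted over the list alone), with Hes1, Sox3 (-0.79) and Gli3 (-0.61) down and Tnc (0.99) the single riser. Their median change was -0.34 (adjusted p = 0.000117; adjusted p = 0.115 with an estimated correlation). Histone genes fell in 4 of 10 (5 adjusted over the list alone), H1f2 (-0.79) and H2ax (-0.35) first. As a group they had a median of -0.19 (adjusted p = 0.00171; adjusted p = 0.184 with an estimated correlation). Glutamatergic synapse genes were higher, with 9 of 18 risen and 1 fallen (13 and 1 adjusted over the list alone) and Gria2 (0.77), Camk2b (0.71), Grm5 (0.73) and Snap25 (0.45) in front. The list's median was 0.34 (adjusted p = 8.85e-06; adjusted p = 0.235 with an estimated correlation). Ion channel and GABA receptor genes rose in 7 of 16 and fell in 1 (9 and 1 adjusted over the list alone), Scn2a (0.78) and Gabbr1 (0.32) up and Kcna1 (-0.51) down. The median of these genes was 0.38 (adjusted p = 2.29e-05; adjusted p = 0.139 with an estimated correlation). Cortical layer genes rose in 7 of 15 (8 adjusted over the list alone), led by Rorb (1.00), Rgs4 (0.72), Lmo4 (0.52) and Crym (0.86). The members had a median of 0.31 (adjusted p = 0.000575; adjusted p = 0.115 with an estimated correlation). Running and neurotrophic factor genes rose in 4 of 10 (6 adjusted over the list alone), Npy (0.84), Ntrk2 (0.57), Grin2b (0.73) and Igf1 (0.97). Across members the median was 0.45 (adjusted p = 0.000541; adjusted p = 0.184 with an estimated correlation). Striatal genes rose in 3 of 11 (4 adjusted over the list alone), Foxp1 (0.66), Drd2 (0.79) and Rxrg (1.00). Their median change was 0.46 (adjusted p = 0.00065; adjusted p = 0.415 with an estimated correlation). Oligodendrocyte lineage genes rose in 3 of 8, namely Olig1 (1.03), Pdgfra and Gpr17 (at least 1.52, with 2 MC arrays under the floor). As a group they had a median of 0.48 (adjusted p = 0.0115; adjusted p = 0.317 with an estimated correlation). Thyroid hormone genes rose in 2 of 5 (3 adjusted over the list alone), Dio2 (1.44) and Crym, and VPM replicate 3, with the choroid plexus signal, stood apart with a score of 2.41 against 0.57 and 0.80. The list's median was 0.86 (adjusted p = 0.00381; adjusted p = 0.154 with an estimated correlation). GABAergic interneuron genes were all 12 higher with 1 risen, Npy, but the VPM scores of 0.04, 0.85 and 0.35 overlapped the MC scores of 0.34, -0.58 and 0.23. The median of these genes was 0.36 (adjusted p = 0.0192; adjusted p = 0.577 with an estimated correlation). MC replicate 2, the lowest of those MC scores, was also the lowest MC array for the striatal (-0.41) and oligodendrocyte (-0.37) scores. The deacetylase inhibitor responders did not pass as a list (adjusted p = 0.52).

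**Figure D2:**
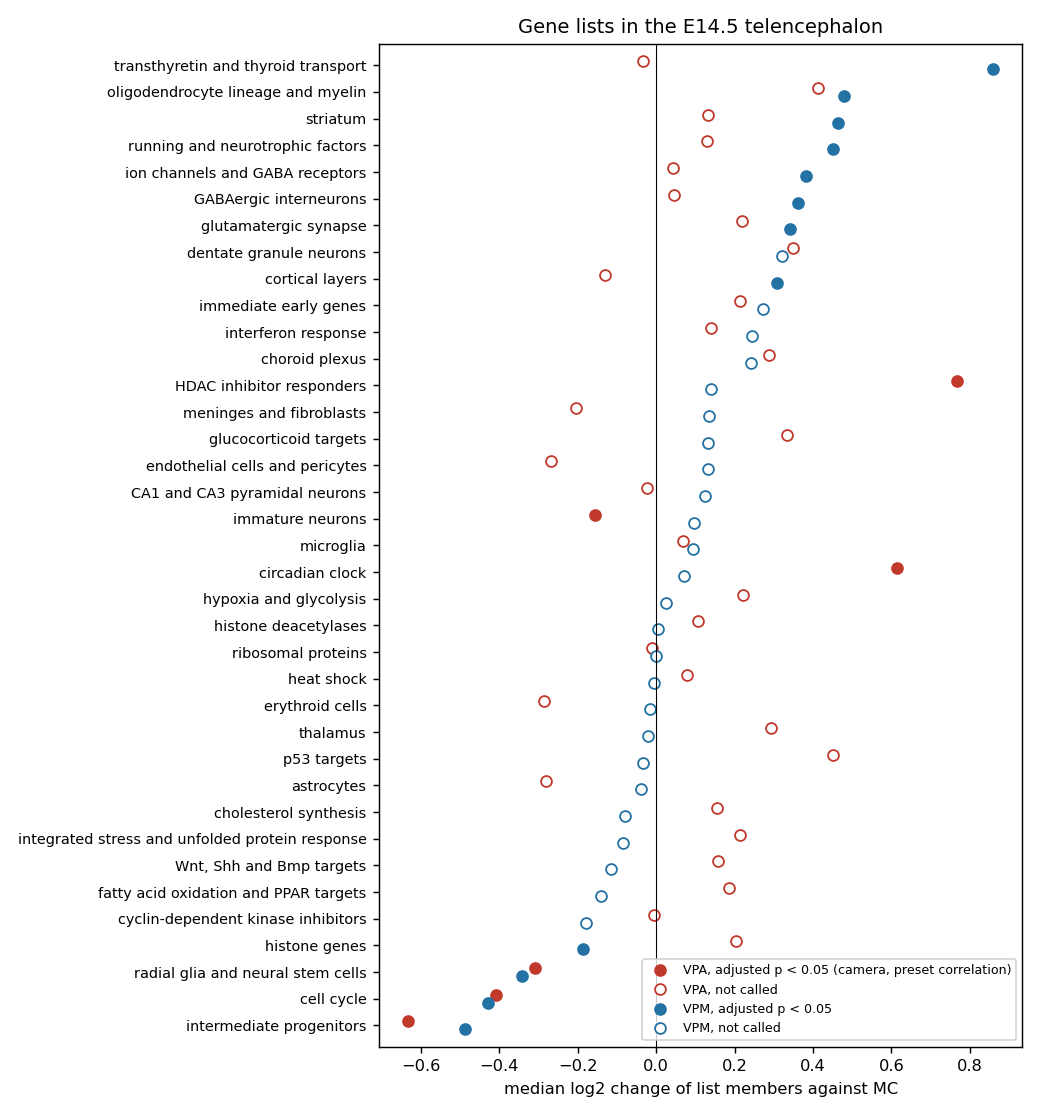
Median log2 change of the members of each gene list against MC in the E14.5 telencephalon, for VPA and VPM; filled points passed an adjusted p of 0.05 by camera with the preset correlation. The cell cycle list lay at -0.41 with VPA and -0.43 with VPM, and the list of deacetylase inhibitor responders at 0.77 with VPA.

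VPA and VPM were then set against each other to ask where the drug and its amide differed. H1f2 stood at 6175 ± 683 in VPA and 801 ± 32.3 in VPM (n = 3 each), a log2 difference of 2.94 (95% interval 2.73 to 3.15, limma adjusted p 8.19e-09). Kmt5b was lower in VPA by a log2 difference of -2.50 (interval -2.65 to -2.34), and Vxn stood at 259 ± 6.60 against 1017 ± 8.59 (-1.97). Genes higher in VPA included H2-Ab1, below the floor in VPM, Hspa1b (3.06), the transcriptional regulator gene Cited1 (2.96), Hspa1a (2.78), the retinoic acid binding protein gene Crabp2 (2.69), Efhd1 (2.51), Ell2 (2.49), Sesn2 (2.48), Gsta4 (2.47) and Tspan33 (2.47). Lower in VPA were St6gal2 (-2.32), Dis3l (-2.32), Atxn7l2 (-2.25), the synaptic protein gene Lgi1 (-2.18), Slc25a26 (-2.17), St8sia3 (-2.13), Masp1 (-2.06), Arhgap42 (-2.06), Nxph2 (-2.02) and Nsmaf (-1.93). The differences of Cited1, Hspa1a and Ell2 are lower bounds, since VPM arrays lay under the floor. VPA and VPM differed in 6033 genes, 3038 higher and 2995 lower in VPA, and the groups did not overlap in 60.7% of genes against 10% by chance.

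Immature neuron genes were lower in VPA than in VPM in all 19 members, 16 of them past the threshold (18 adjusted over the list alone), with Nhlh2 (-0.96), Tbr1 (-1.08), Bcl11b (-0.41) and Dcx (-0.37) first. The members had a median of -0.24 (adjusted p = 9e-04; adjusted p = 0.219 with an estimated correlation). Genes of the integrated stress and unfolded protein response were higher in 11 of 18, led by Chac1 (1.62), Sesn2 and Sdf2l1 (1.17). Across members the median was 0.27 (adjusted p = 0.0165; adjusted p = 0.219 with an estimated correlation). Of 12 p53 targets 9 were higher and 2 lower (10 and 2 adjusted over the list alone), Bbc3 (1.26) higher and Plk2 (-0.69) lower. Their median change was 0.52 (adjusted p = 0.0182; adjusted p = 0.219 with an estimated correlation). Deacetylase inhibitor responders were higher in 8 of 14 and lower in 2. As a group they had a median of 0.75 (adjusted p = 0.0324; adjusted p = 0.229 with an estimated correlation). Histone genes were higher in 6 of 10 and lower in 1 (7 and 1 adjusted over the list alone), H1f10 (0.84) and H2ax (0.49) higher and Macroh2a2 (-1.10) lower. The list's median was 0.38 (adjusted p = 0.0182; adjusted p = 0.247 with an estimated correlation). Cholesterol synthesis genes were higher in 10 of 20, with Stard4 (0.90), Mvd (0.67) and Dhcr7 (0.66) first, and clock genes in 8 of 13 (both adjusted p = 0.0182; adjusted p = 0.219 with an estimated correlation; medians 0.25 and 0.52). Cortical layer genes were lower in 9 of 15 (10 adjusted over the list alone), Fezf2 (-1.26) and Crym (-1.57) among them. The median of these genes was -0.44 (adjusted p = 0.0182; adjusted p = 0.219 with an estimated correlation). Endothelial and pericyte genes were lower in 7 of 12, Kcnj8 (-1.86), Esam (-0.93) and Cldn5 (-0.80) first. The members had a median of -0.40 (adjusted p = 0.0188; adjusted p = 0.365 with an estimated correlation). The thyroid hormone genes (4 of 5 lower, median -1.43, adjusted p = 0.0326), the heat shock genes (7 of 13 higher and 1 lower, median 0.18, adjusted p = 0.0429) and the hypoxia and glycolysis genes (9 of 17 higher and 2 lower, median 0.38, adjusted p = 0.0476) completed the called lists, at an adjusted p of 0.229, 0.219 and 0.322 with an estimated correlation. For the thyroid hormone genes VPM replicate 3 again stood apart. The cell cycle list (adjusted p = 0.677), the intermediate progenitors (0.209) and the radial glia genes (0.918) did not pass between VPA and VPM.

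Across genes, the VPA and VPM changes from MC at E14.5 correlated with a Pearson r of 0.19 (Spearman 0.19). Simulated unchanged groups sharing the MC arrays gave 0.497. The simulation held no drug effect, and changes made by 1 drug alone lower r (SD of the changes 0.525 for VPA and 0.255 for VPM). The lower real r therefore does not show that the responses were less alike than chance. Genes are not independent replicates. The covariance was 0.0255 against 0.0116 simulated. Of 1266 VPM calls, 777 were also VPA calls: 245 higher in both (169.1 if the call lists were independent), 284 lower in both (171.6) and 248 in opposite directions. Rises and falls were near equal in number in both call lists (2996 and 2965 for VPA, 625 and 641 for VPM). Independent lists would thus give about as many opposite as shared directions, so the 248 were fewer than that, not an excess. The shared controls may lower that number too. Part of the excess of shared directions may come from the shared controls, since a split of 3 MC arrays leaves a single array on 1 side. Of the 5961 VPA calls, 4696 (78.8%) also differed between VPA and VPM; the 95% interval of a gene's VPA minus VPM difference had a median half-width of 0.21 on the log2 scale. H1f2 went up with VPA (2.15) and down with VPM (-0.79), while Npy went down with VPA (-0.28) and up with VPM (0.84).

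The E18.5 forebrain was compared to ask what remained 4 days after the last dose, with VPA first. Ttr, the transthyretin gene of the choroid plexus, stood at 21090 ± 3606 in MC and at 1885 ± 2204 in VPA (n = 3 each, log2 change -4.35, limma adjusted p 0.0149). Eomes, a transcription factor gene of intermediate progenitors, fell from 1047 ± 66.4 to 583 ± 48.8 (-0.85, adjusted p 0.00183), and Neurog2, at 709 ± 128 in MC, fell too (-0.93). Klf9, a hormone-responsive transcription factor gene, rose from 650 ± 28.6 to 1119 ± 120 (0.78, adjusted p 0.00183), and the postsynaptic gene Nrgn from 1400 ± 90.6 to 2212 ± 40.5 (0.66, adjusted p 0.00348). Other choroid plexus and ependymal genes fell with Ttr: Kcne2 at least 8.61-fold (below the floor in VPA), Aqp1 (-2.51), Folr1 (-2.27), Ecrg4 (-1.74), Sostdc1 (-1.36), Clic6 (-1.27) and the cilia gene Cfap126 (-1.14). The fall of Aqp1 is a bound too, with 1 VPA array under the floor. Alas2 (-1.10) and Zfp503 (-0.76) fell as well. Further rises were in the astrocyte water channel gene Aqp4 (0.73), Ptk2b (0.72), Fam107a (0.62), Lpl (0.57), Tbc1d5 (0.57), the dendritic gene Ddn (0.55), Rprml (0.54), Egr1 (0.52), Kcnh3 (0.51) and Sstr4 (0.51).

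Of 11515 genes tested in the forebrain, 243 changed with VPA, 124 upward and 119 downward, 37 of them by 1.5-fold or more and 16 of those downward by 2-fold or more. The unadjusted p was under 0.05 in 1845 genes, and the groups did not overlap in 22.2% against 10% by chance. The count rested on single arrays: it was 36 without VPA replicate 1 and 172 without VPA replicate 3. Without MC replicates 1, 2 and 3 it was 99, 69 and 66, and without VPA replicate 2 it lay between 99 and 172. With the values as deposited it was 25, 1 higher and 24 lower. It was 58 without a filter, 157 without a trend in the moderation and 153 with only the 2 groups. Without a filter Eomes, Kcne2, Klf9 and Nrgn kept their calls, and the other 20 genes named for this comparison, Ttr and Neurog2 among them, lost theirs. With the values as deposited every named rise lost its call, Klf9 (limma adjusted p 0.335) and Nrgn (0.99) included. So did Eomes (0.195), Neurog2 and Zfp503. Fam107a, Kcnh3 and Sstr4 lost their call without any 1 of the 6 arrays; Aqp1, Aqp4, Cfap126, Clic6, Egr1, Lpl, Ptk2b, Rprml, Sostdc1, Tbc1d5 and Zfp503 lost it without at least 1 of them, and Ttr without MC replicate 2, MC replicate 3 or VPA replicate 1 (adjusted p 0.0569, 0.0577 and 0.0705).

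Cell cycle genes were lower in 28 of 31 in the VPA forebrain, and 9 fell (19 adjusted over the list alone), with Cdca8 (-0.41), Top2a (-0.44), Cdk1 (-0.41) and Ube2c (-0.42) first. Across members the median was -0.26 (adjusted p = 5e-14; adjusted p = 0.0757 with an estimated correlation). All 12 intermediate progenitor genes were lower, and Eomes, Neurog2, Gadd45g (-0.56) and Insm1 (-0.47) led the 6 that fell (7 adjusted over the list alone). Their median change was -0.35 (adjusted p = 1.08e-08; adjusted p = 0.0757 with an estimated correlation). Choroid plexus genes fell in 7 of 9 (8 adjusted over the list alone), Calml4 (-2.47 or lower, with 2 VPA arrays under the floor), Folr1 and Sostdc1 among them and Otx2 below the floor in VPA. As a group they had a median of -2.11 (adjusted p = 1.59e-10; adjusted p = 0.0906 with an estimated correlation). Radial glia genes fell in 2 of 20 (6 adjusted over the list alone), Pax6 (-0.41) and Sox2 (-0.32). The list's median was -0.16 (adjusted p = 0.00134; adjusted p = 0.0935 with an estimated correlation). Glutamatergic synapse genes were higher in 16 of 18, with 1 risen, Nrgn, or 8 adjusted over the list alone. The median of these genes was 0.16 (adjusted p = 1.46e-05; adjusted p = 0.0787 with an estimated correlation). Cholesterol synthesis genes were higher in 19 of 20, with 1 risen, Msmo1 (0.19), or 8 adjusted over the list alone. The members had a median of 0.14 (adjusted p = 7.64e-06; adjusted p = 0.0787 with an estimated correlation). The ion channel list (1 of 19 risen, Scn2a at 0.23, or 2 adjusted over the list alone; adjusted p = 0.000184) and the pyramidal neuron list of CA1 and CA3 (1 of 10 risen, Prkcb at 0.28, or 2 adjusted over the list alone; adjusted p = 0.000377) were higher, at an adjusted p of 0.0837 and 0.0757 with an estimated correlation. Astrocyte genes rose in 1 of 13, Aqp4 (2 adjusted over the list alone; adjusted p = 0.00221), and oligodendrocyte lineage genes in 2 of 12, Olig1 (0.45) and Cnp (0.39) (5 adjusted over the list alone; adjusted p = 0.00497), both at an adjusted p of 0.0828 with an estimated correlation. Erythroid genes were lower in 3 of 3 with Alas2 the only faller (adjusted p = 0.00497; adjusted p = 0.0834 with an estimated correlation), and histone genes in 7 of 10 with 2 fallers (4 adjusted over the list alone; adjusted p = 0.0105; adjusted p = 0.0837 with an estimated correlation). Of the lists tested, 15 of 38 passed with the preset correlation and 0 with an estimated one.

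**Figure D3:**
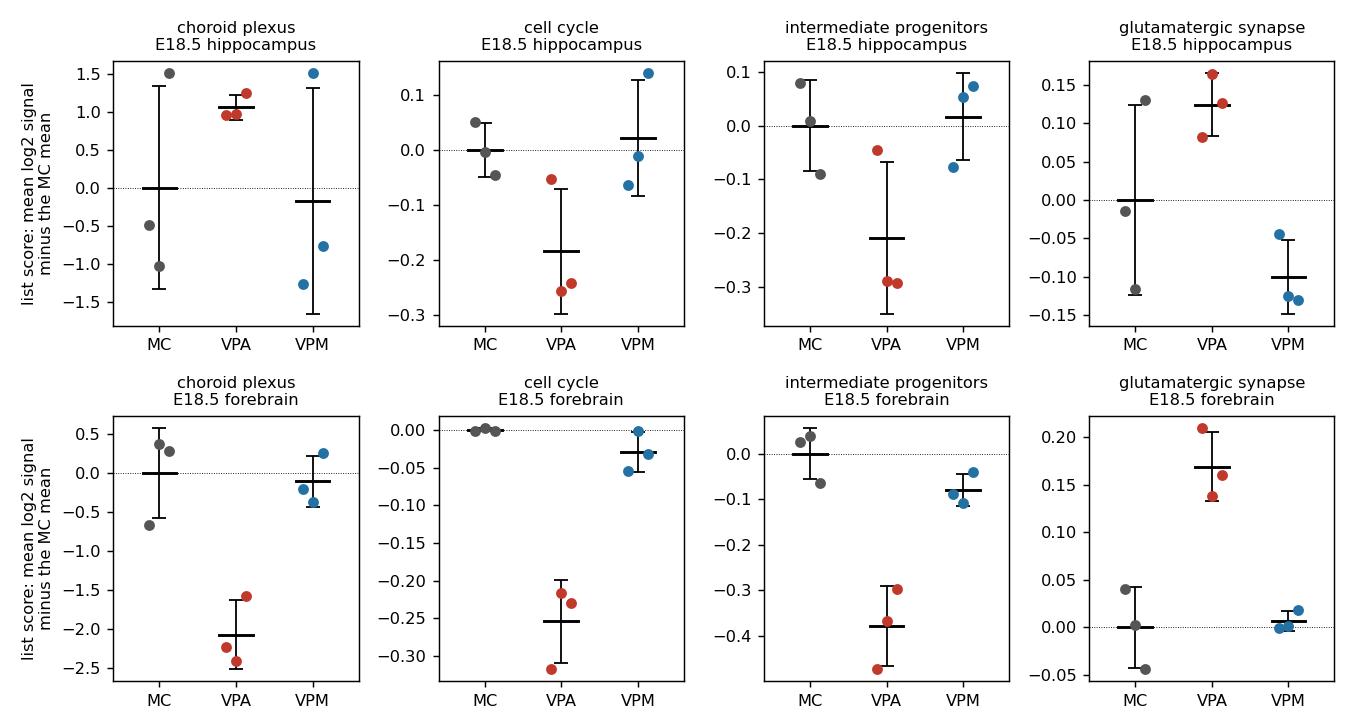
List scores (mean log2 signal of the members minus the MC mean) of single arrays in the E18.5 hippocampus and forebrain by dosing group, with group means. The choroid plexus score of the forebrain averaged -2.07 in VPA, and in the hippocampus the MC arrays alone spread from -1.02 to 1.51.

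VPM in the E18.5 forebrain gave 0 calls by limma, with 626 of 11515 genes at an unadjusted p under 0.05, where chance gives 576. The 5 genes with the smallest p did not pass: H1f2 (-0.55, adjusted p 0.0779), Apold1 (-0.97, 0.107), Tfrc (0.35, 0.107), Fbxl4 (-0.42, 0.32) and Dazap1 (-0.25, 0.382). As lists, 6 of 38 were lower with VPM, and 0 of their members passed: histone, intermediate progenitor, immediate early, endothelial, erythroid and hypoxia genes (adjusted p = 0.0303 for hypoxia and 0.0489 for the others; adjusted p = 0.521 or more with an estimated correlation). Adjusted over the list alone, at most 1 member of a list fell, and 1 immediate early gene rose. VPA differed from VPM there in 61 genes, 28 higher and 33 lower in VPA. Kcne2 was below the floor in VPA against 254 ± 105 in VPM, Ttr stood at 20332 ± 1812 in VPM (-4.31), and Aqp1 (-2.21), Folr1 (-2.16), Ecrg4 (-1.64), Sostdc1 (-1.15), Neurog2 (-0.84), Alas2 (-0.83), Eomes (-0.69), the corepressor gene Rcor2 (-0.59), Ezr (-0.55) and Prdm16 (-0.50) were lower. Higher in VPA were Lor (0.70), Klf9 (0.67), the potassium channel gene Kcna6 (0.60), Nrgn (0.60), Ccn3 (0.60), Ddn (0.57), Rprml (0.50), St6galnac6 (0.49), Tbc1d5 (0.46), Prrt1 (0.46), the muscarinic receptor gene Chrm1 (0.43) and Abr (0.39). Among these genes only Kcne2 kept its call without each single array. Without a filter all of these genes lost their calls, Kcne2 included (limma adjusted p 0.0875), and the count fell to 7. The count was 2 without VPA replicate 1 or VPM replicate 1, 8 without VPA replicate 2, 39 without VPA replicate 3, and 7 and 4 without VPM replicates 2 and 3. With the values as deposited it was 21, 2 higher and 19 lower. Cell cycle genes were lower in VPA than in VPM in 30 of 31, 4 past the threshold, Ube2c, Cdca8, Ccnb2 and Cdk1 (12 adjusted over the list alone; median -0.22, adjusted p = 4.32e-15; adjusted p = 0.0689 with an estimated correlation), and choroid plexus genes in 9 of 9, 6 past the threshold (8 adjusted over the list alone; adjusted p = 4.73e-12; adjusted p = 0.104 with an estimated correlation). The VPA and VPM changes correlated across genes at r 0.43 against 0.491 simulated, with covariances of 0.0108 and 0.00972. Here too the simulation held no drug effect, so the lower real r does not show responses less alike than chance.

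The hippocampus at E18.5 was compared because the study followed the hippocampus into adult life. Tfrc, the transferrin receptor gene, rose with VPM from 758 ± 23.0 to 1227 ± 29.6 (n = 3 each, log2 change 0.69, limma adjusted p 0.0166), the single call of 11542 genes. It lost that call without any 1 of the 6 arrays (adjusted p 0.0553 to 0.195). With VPA, Tfrc had the smallest p and did not pass (1128 ± 105, 0.57, adjusted p 0.0804), nor did Vldlr (0.46, 0.0804), the metallothionein gene Mt2 (0.50, 0.0928), Clec2l (0.55, 0.1) and Ddit4l (0.89, 0.1). With VPM the next genes, Id1 (-0.57, adjusted p 0.0806), Apold1 (-1.16, 0.0943), Slc38a2 (0.29, 0.236) and Arrdc3 (-0.41, 0.236), did not pass. VPA against VPM gave 0 calls, with Apoe (0.55), Ddit4l (0.94), Scg2 (0.84), Lhfpl3 (0.79) and Kcnd2 (0.45) at an adjusted p of 0.0725. The unadjusted p was under 0.05 in 1504 genes for VPA (0 calls by limma), 1196 for VPM and 1706 between them, where chance gives 577. With the values as deposited, VPA gave 60 calls, 55 of them higher, while the median of all genes shifted by 0.15. The counts stayed between 0 and 4 when single arrays were left out.

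Several lists passed in the hippocampus although 0 of their genes did with VPA. Cell cycle genes were lower in 31 of 32, with Top2a (-0.27), Cdk1 (-0.32) and Mcm2 (-0.34) first and 0 passing adjusted over the list alone. Across members the median was -0.17 (adjusted p = 2.68e-06; adjusted p = 0.399 with an estimated correlation). Radial glia genes (18 of 20 lower, 4 fell adjusted over the list alone, Vim -0.37; adjusted p = 0.000838) and intermediate progenitor genes (10 of 13 lower, 5 fell adjusted over the list alone, Eomes -0.56; adjusted p = 0.00464) were lower, at an adjusted p of 0.445 and 0.392 with an estimated correlation. Interferon response genes were higher in 7 of 8, Bst2 (0.79), Ifitm3 (0.56) and Oasl2 (0.77) first (4 rose adjusted over the list alone). Their median change was 0.45 (adjusted p = 0.000534; adjusted p = 0.357 with an estimated correlation). Meningeal and fibroblast genes were higher in 13 of 14, Ptgds (1.69) first (0 adjusted over the list alone). As a group they had a median of 0.38 (adjusted p = 0.000838; adjusted p = 0.51 with an estimated correlation). Choroid plexus genes were higher in 9 of 10 (0 adjusted over the list alone; median 1.22, adjusted p = 0.0283; adjusted p = 0.598 with an estimated correlation), but the score of the 3 MC arrays had an SD of 1.33 and an exact two-sided permutation p of 0.4, where 3 against 3 cannot go below 0.1. The falls lay in VPA replicates 2 and 3, with cell cycle scores of -0.26 and -0.24 and intermediate progenitor scores of -0.29 in both, while replicate 1 (-0.05 for each list) lay near the lowest MC array (-0.05 and -0.09). The female pattern was seen in the same VPA replicates 2 and 3 and in 0 of the 3 MC arrays, so fall and sex coincided array by array. The 18S ribosomal RNA control read 11030 to 20360 in VPA against 5065 to 7172 in MC. The lists were not adjusted for either. Between VPA and VPM, deacetylase inhibitor responders were higher in VPA in 12 of 13, Hspa1a (0.97), Mt1 (0.36), Hspa2 (0.76) and Cdkn1a (0.58) first (8 adjusted over the list alone). The list's median was 0.42 (adjusted p = 5.81e-06; adjusted p = 0.116 with an estimated correlation). With VPM against MC, hypoxia and glycolysis genes were lower in 14 of 18, Hk2 (-0.47) and Vegfa (-0.59) first (9 fell adjusted over the list alone; median -0.19, adjusted p = 0.000378; adjusted p = 0.566 with an estimated correlation).

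Whether the VPA effect differed between hippocampus and forebrain at E18.5 was tested as a difference of the changes. By limma, 0 of 11867 genes passed, with 1094 at an unadjusted p under 0.05. Ddit4l had the smallest p (difference 1.10, adjusted p 0.138), followed by Clcn5 (1.00), Ppip5k2 (0.53), Pdcl (0.39) and Pbx3 (1.00), and none passed. The choroid plexus list differed (median 3.34, all 10 members, 8 adjusted over the list alone; adjusted p = 1.45e-08; adjusted p = 0.788 with an estimated correlation), and cholesterol synthesis genes moved less in the hippocampus (median -0.16, 18 of 20 members, 3 adjusted over the list alone; adjusted p = 3.39e-05; adjusted p = 0.286 with an estimated correlation). With the values as deposited 43 genes passed, 38 of them higher in the hippocampus, with a median shift of all genes of 0.16.

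The genes changed by VPA at E14.5 were followed as sets into the later arrays. In the forebrain at E18.5, Klf9 (2.14 at E14.5) and Nrgn (0.93) were higher again, and Eomes (-0.92) and Neurog2 (-0.83) were lower again. Kmt5b, H1f2 and Hspa1a, among the strongest responders at E14.5, did not pass there (0.03, -0.21 and -0.08). As a set, the 2917 genes lower at E14.5 had a median of -0.03 in the forebrain, 55 falling and 16 rising (adjusted p = 0.00729; adjusted p = 0.0119 with an estimated correlation), and 38.9% of them were higher against 53.3% of the other genes. The 2927 genes higher at E14.5 had a median of 0.02, 44 rising and 9 falling (adjusted p = 0.059; adjusted p = 0.0119 with an estimated correlation). Of the 224 forebrain calls that were tested at E14.5 too, 71.9% had the same direction there. In the hippocampus at E18.5, adult hippocampus, adult cortex and P84 hippocampus neither of these sets passed, with adjusted p from 0.074 to 0.664. Of the genes changed 2-fold or more at E14.5, sets added after the data had been seen, the higher set passed in the E18.5 hippocampus (median 0.06, 64.9% higher against 47.7%, adjusted p = 0.00447; unadjusted p = 0.0737 with an estimated correlation). In the forebrain the higher set passed too (median 0.065, camera adjusted p = 0.00172). The lower set did not pass there (median -0.0293, 42.9% higher against 49.8%, camera adjusted p = 0.436).

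In adult hippocampus the study asked whether prenatal VPA left a lasting change and whether running altered it. Not a single gene passed in any of the 5 comparisons of 13479 genes by limma, where chance gives 674 genes at an unadjusted p under 0.05. That count was 1479 for VPA against MC, 1166 for running in MC, 1144 for running in VPA, 566 for VPA+RW against MC+RW and 612 for the interaction. For VPA the smallest p belonged to Lhx3 (-0.93), Cluap1 (-0.76), Cd2bp2 (0.34), Aph1a (0.53) and Bhlhe40 (0.39), all at an adjusted p of 0.237. For running in MC they were Trib2 (0.55, adjusted p 0.0608), Npy (2013 ± 180 to 3061 ± 281, n = 3 each, 0.60, limma adjusted p 0.0786), Fxyd6 (-0.44, 0.0852), Scg2 (0.31, 0.127) and Kdm7a (0.48, 0.139). For running in VPA they were Igfbp6 (0.72, 0.0581), Wdr6 (-0.41, 0.0581), Cdkn1a (0.75), Rab40c (0.81) and the clock gene Arntl (0.60), the last 3 at 0.0741. For VPA+RW against MC+RW they were Rnf185 (0.51), Hs3st2 (-0.69), Usp30 (0.77), Fgf22 and Cd40lg (1.83), at 0.301, and for the interaction Cd40lg (2.70), Polr1a (-0.70), Cog7 (0.97), Usp30 (0.92) and Heca (-0.33), at 0.854. Leaving out single arrays gave at most 4 calls for VPA, 7 for running in MC (without MC+RW replicate 1) and 5 for running in VPA (without VPA+RW replicate 3). The neuron differentiation gene Dcx, a marker of newborn neurons, changed by 0.08 with VPA and by -0.06 with running in MC, and did not pass (adjusted p 0.862 and 0.952).

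Running and neurotrophic factor genes were higher in the hippocampus of MC runners in 10 of 12, with Npy, Nrn1 (0.25), Ntrk2 (0.20) and Bdnf (0.30) first (0 rose, 4 adjusted over the list alone). The median of these genes was 0.15 (adjusted p = 0.00148; adjusted p = 0.0948 with an estimated correlation). Their score in MC+RW was 0.16 ± 0.011 above MC, whose SD was 0.039, with an exact two-sided permutation p of 0.1, the lowest that 3 against 3 allows. Running in VPA did not pass for this list (8 of 12 higher, median 0.07, adjusted p = 0.239), nor did the interaction (adjusted p = 0.173). Heat shock genes were higher with running in 12 of 13, Hsph1 (0.34) first (2 rose adjusted over the list alone; adjusted p = 0.00212; adjusted p = 0.665 with an estimated correlation). In VPA runners clock genes were lower in 12 of 16, Nr1d2 (-0.50) and Ciart (-1.21) among them and Arntl higher (2 rose and 7 fell adjusted over the list alone). The members had a median of -0.24 (adjusted p = 0.00541; adjusted p = 0.758 with an estimated correlation). VPA against MC without running gave 5 called lists. Glucocorticoid target genes went both ways, with Klf9 (0.19) and Tsc22d3 (0.39) higher and Cdkn1a (-0.56) lower (6 rose and 1 fell adjusted over the list alone; median 0.13, adjusted p = 0.0228), and the glutamatergic synapse list had a median of 0.08 (adjusted p = 0.0282), both at an adjusted p of 0.882 with an estimated correlation. Astrocyte, cholesterol synthesis and ribosomal protein genes were higher in 12 of 15, 17 of 20 and 15 of 16, with 0 passing adjusted over the list alone (adjusted p = 0.0228, 0.0228 and 0.02; adjusted p = 0.882 with an estimated correlation for each). With quantile normalization 0 of the 5 lists passed, and the camera direction of the glutamatergic synapse list turned (median 0.01). With running, VPA against MC had lower meningeal genes in 14 of 14, Ogn (-1.02) first (median -0.39, adjusted p = 0.000231), and higher dentate granule neuron genes in 11 of 13, Stxbp6 (0.25) first (median 0.09, adjusted p = 0.0129), with 0 members passing adjusted over the list alone and an adjusted p of 0.881 with an estimated correlation for both.

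In adult cortex the same comparisons were made to see whether effects extended beyond the hippocampus. Epcam, an epithelial adhesion gene, rose with VPA from 152 ± 19.1 to 370 ± 23.1 (n = 3 each, log2 change 1.29, limma adjusted p 0.0246), the only call of 13621 genes (1422 at an unadjusted p under 0.05); it did not pass in the hippocampus, where it went the other way (-0.80, adjusted p 0.626). The next genes did not pass: Dlgap3 (-0.38, 0.0693), Selenok (0.48, 0.0693), Ggt7 (2.23, 0.0872) and Vtn (0.37, 0.11). Running in MC lowered the kinase gene Pim3 (-0.50, adjusted p 0.0216) and raised the doublecortin-like kinase gene Dclk1 (0.31, 0.0322), while Pcnt (0.76), Nrn1 (0.32) and Mmp7 (-2.62) did not pass (adjusted p 0.0534, 0.0534 and 0.059). The count was 128 without MC+RW replicate 3, and 0 without MC replicate 1, MC replicate 3 or MC+RW replicate 2. Running in VPA gave 0 calls by limma (851 at an unadjusted p under 0.05), with Pim3 (-0.45, adjusted p 0.0677), Nptx2 (0.61), Gsk3b (-0.34), Coq10b (-0.43) and Sgk1 (-0.80) first. VPA+RW against MC+RW gave 3 calls, all lower: the centrosome gene Pcnt (476 ± 18.7 against 1024 ± 13.4, -1.11, adjusted p 0.00235), Cdk18 (-0.78, 0.0442) and Gsk3b (-0.39, 0.0442), with Csnk1e (-0.37) and Mmp7 (2.45) not passing. That count was 11 without MC+RW replicate 3 and 1 without VPA+RW replicate 1 or 3. The interaction gave 0 calls by limma (848 at an unadjusted p under 0.05), with Pcnt (-1.06), Gsk3b (-0.52), Mmp7 (3.49), Slc7a5 (-0.64) and Ggt7 (-2.57) first, so a VPA effect that depended on running was not shown for any gene. Epcam was not called without MC replicate 1, MC replicate 3 or any 1 of the VPA arrays (adjusted p 0.0717 to 0.168). Pim3 and Dclk1 lost their calls without any 1 of the MC arrays or MC+RW replicate 2, and Cdk18 and Gsk3b without any 1 of the VPA+RW arrays or MC+RW replicate 1. Other settings ended calls as well. Epcam was not called without a filter or without a trend, and Pcnt not without a filter. Pim3 and Dclk1 were not called as deposited, without a trend or with the replicate block, nor Dclk1 with quantile normalization or only the 2 groups. Cdk18 and Gsk3b were not called as deposited, without a filter, without a trend, with the block or with only the 2 groups. Other probe sets of the called genes went the same way in 7 of 10 for running in MC and in 2 of 6 for VPA+RW against MC+RW. The as-deposited values shifted the median of all genes by -0.10 for VPA and 0.13 for the interaction.

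Glucocorticoid target genes were higher with VPA in the adult cortex in 14 of 15, with Sgk1 (0.65), Tsc22d3 (0.33), Per1 (0.74) and Nfkbia (0.32) first (5 rose adjusted over the list alone). Across members the median was 0.19 (adjusted p = 0.000113; adjusted p = 0.321 with an estimated correlation). Meningeal genes (12 of 14 higher, 2 rose adjusted over the list alone, Bgn 0.47) and cholesterol synthesis genes (16 of 20 higher, Hmgcs1 0.20) had an adjusted p of 0.00151, which became 0.621 and 0.205 with an estimated correlation. With running in MC, heat shock genes were higher in 10 of 13 (Hsph1 0.33, 3 rose adjusted over the list alone; adjusted p = 0.00344) and running and neurotrophic factor genes in 10 of 12 (Nrn1, Npy at 0.24, 4 rose adjusted over the list alone; adjusted p = 0.00944), both at an adjusted p of 0.342 with an estimated correlation.

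The P84 hippocampus set asked the same question in a second cohort with 4 arrays per group. By limma 0 of 13051 genes passed, and 645 had an unadjusted p under 0.05, where chance gives 653. The immediate early gene Arc had the smallest p, 1441 ± 53.5 in MC and 1887 ± 160 in VPA (n = 4 each, log2 change 0.39, limma adjusted p 0.411), followed by Nr4a1 (0.34), Ric8a (-0.34), Chrac1 (-0.49) and Klf1 (-0.95), and none passed. Immediate early genes were higher in 17 of 20, Arc, Nr4a1, Fos (0.54) and Egr1 (0.23) first (5 rose adjusted over the list alone; median 0.13, adjusted p = 3.95e-06; adjusted p = 0.552 with an estimated correlation), and their score was higher by 0.16 ± 0.08 against an MC SD of 0.058 (exact two-sided permutation p 0.0286, the lowest that 4 against 4 allows). Dentate granule neuron genes were lower in 12 of 12, with C1ql2 (-0.27), Plekha2 (-0.30), Stxbp6 (-0.31) and Dsp (-0.47) first (6 fell adjusted over the list alone; median -0.28, adjusted p = 1.28e-07; adjusted p = 0.552 with an estimated correlation), at a score of -0.27 ± 0.19 (exact two-sided permutation p 0.0857). For the dentate list VPA replicate 4 scored -0.0096, within the MC scores of -0.0911 to 0.1374. That array also stood apart for thalamic genes, with a score of 0.5861 against at most 0.1098 in the other arrays. Ribosomal protein genes were higher in 15 of 16 by a median of 0.06 (0 adjusted over the list alone; adjusted p = 0.00316; adjusted p = 0.552 with an estimated correlation). The values as deposited gave 10 calls and shifted the median of all genes by -0.18.

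**Figure D4:**
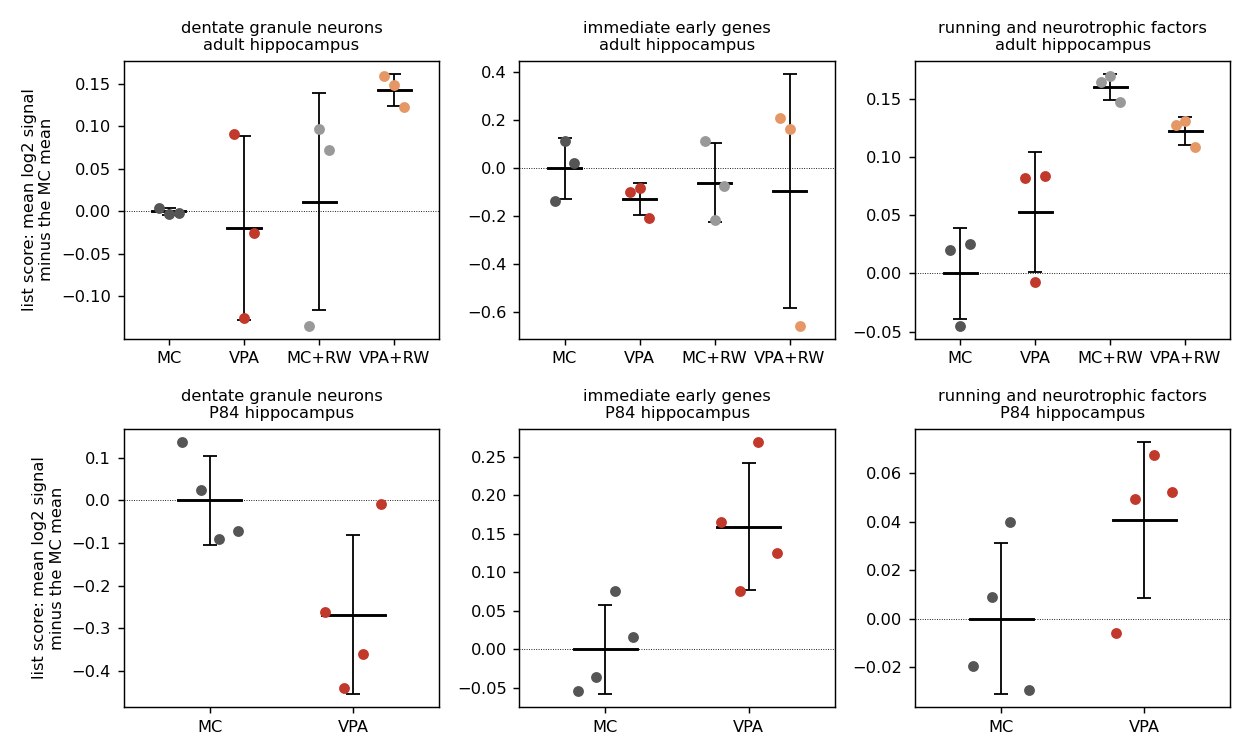
List scores (mean log2 signal of the members minus the MC mean) of single arrays in the adult and P84 hippocampus by group, with group means; +RW marks the running wheel. In the P84 set the dentate granule neuron score averaged -0.27 and the immediate early gene score 0.16 in VPA.

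The 2 adult hippocampus cohorts did not share a VPA response across genes: the log2 changes of 12952 genes correlated at a Pearson r of -0.02 (Spearman -0.002), and 50.6% had the same sign. Genes with an unadjusted p under 0.05 in both and the same sign numbered 34, where 35.2 would come from independent lists. Tested as a difference of the VPA effects over 13656 genes, only Ggt7 passed, with a log2 difference of -2.02 (P84 minus the running cohort, adjusted p 1.99e-06), since it stood at 979 ± 108 in VPA and 236 ± 39.3 in MC of the running cohort (n = 3 each) and at 1157 ± 70.6 and 1127 ± 28.6 at P84 (n = 4 each by limma). Ciart (-1.15), Ric8a (-0.45), H2-Eb2 (1.04) and Cnn2 (0.89) came next and did not pass (adjusted p 0.277). The dentate granule neuron list was lower (median -0.27) and the immediate early gene list higher (0.22) at P84 than in the running cohort in their VPA effect, both at an adjusted p of 0.00243 and of 0.912 with an estimated correlation, with 3 and 5 members passing adjusted over the list alone. The as-deposited values shifted the median of this difference by -0.12.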

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

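The test for less blood in the VPM tissue, the test for choroid plexus reduced in the whole brain and both Ggt7 tests were chosen only after the result was seen, and the criteria of the choroid and Ggt7 variant tests were changed after that.

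At E14.5 with VPM, the cell cycle and progenitor lists were lower and the glutamatergic synapse and ion channel lists higher at the preset correlation only (lowest adjusted p 0.115 with an estimated one), and the embryonic globins Hbb-y and Hba-x fell. The VPM embryos may have been further along in development than the MC embryos. The VPM change correlated across genes with the MC difference between E18.5 forebrain and E14.5 telencephalon at 0.615, single arrays at 0.466 to 0.572. MC arrays set against each other gave -0.187 to 0.267, and the VPA change at E14.5 gave 0.161, within that range. This axis joins stage with tissue, and a loss of progenitors at the same stage would raise the correlation too. Choroid plexus tissue in VPM replicate 3 was tested and set aside, since the cell cycle median without that array was -0.395. Less blood was set aside as well, since the later globin gene Hba-a2 changed by -0.227 only (adjusted p 0.5) and Alas2 rose. Whether VPM speeded development or the VPM embryos were older when taken cannot be told from arrays of 1 age.

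In the E18.5 forebrain, the choroid plexus and cell cycle lists were lower with VPA at the preset correlation only (lowest adjusted p 0.0757 with an estimated one). For the choroid plexus, different amounts of that tissue taken with the forebrain could account for the fall, but the test cannot decide it. Its genes also moved together within groups of the E18.5 hippocampus (median correlation of a member with the others 0.945). A true loss of the tissue would give the same. Scaled Ttr was 236.9 to 4389 in the VPA forebrains, against 17010 to 23860 in MC and 19260 to 22420 in VPM. A reduction in VPA-exposed brains as a whole stays open, since the hippocampal score was higher in VPA by 1.06, within the MC SD of 1.335. Whether the choroid plexus carried the cell cycle fall was not settled. Its slope within hippocampal groups predicted -12.5% of it, but a slope from another tissue, with no interval, cannot exclude this. A later stage of the VPA forebrains might account for the cell cycle fall: the change correlated with the same difference of stages at 0.365, against -0.0922 to 0.0952 between MC arrays. VPM, with 0 genes called in the forebrain, gave 0.107, above that range as well. The axis again joins stage with tissue, and a loss of progenitors at the same stage would raise the correlation too. A drug effect on maturation would look the same.

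Ggt7 differed between the adult cohorts in its VPA effect (adjusted p 1.99e-06). A lasting rise from prenatal VPA was set aside, since the P84 change was 0.036 and the change with running -0.29. A variant carried by some mice of the running cohort could give the pattern: the 3 VPA mice read 855 to 1046 in the hippocampus, MC runners ranged from 150 to 563, and the cortex arrays followed with a correlation of 0.827 over 12 deviations. In 118 reassignments of the array numbers within groups, a share of 0.091, the correlation was as high, but with a single array standing apart in each running group the test had little room to fall under 0.05. It decides nothing, and the variant stays open.

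Single arrays stood out by Dixon's ratio (34 measures tested, about 1 in 20 groups by chance) in the P84 set: Nr4a1 in MC (0.935), Ttr in MC (0.923) and in VPA (0.924), and the deposited trimmed mean in VPA (0.897). The VPA by running interaction passed for the glucocorticoid targets in adult hippocampus (adjusted p 0.00629) and in adult cortex (0.0203), and in cortex for meningeal genes (0.0203), hypoxia genes (0.0261) and erythroid genes (0.0263). The VPA effect differed between hippocampus and forebrain at E18.5 for choroid plexus genes (1.45e-08), cholesterol synthesis (3.39e-05), ribosomal proteins (0.0022) and GABAergic interneurons (0.0276). Between the adult cohorts it differed for immediate early genes and dentate granule neuron genes (both 0.00243). With an estimated correlation 0 of these lists passed, and the lowest adjusted p was 0.798 and 0.445 for the interactions in hippocampus and cortex, 0.286 between the tissues and 0.912 between the cohorts. The 18S ribosomal RNA control probe set read 2.45 times as high in the VPA hippocampus at E18.5 as in MC.

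Other splits of the samples were too few for a share under 0.05 wherever 3 arrays met 3. At E14.5 only 1 of 10 splits, the real one, reached each real count (5961, 1266 and 6033), and the highest other calls numbered 0, 1 and 0. In the forebrain that was 1 of 10 for VPA (243 against 1) and for VPA against VPM (61 against 2), and 10 of 10 for VPM. In the E18.5 hippocampus it was 10, 2 and 10 of 10, with 0, 1 and 4 as the highest others, and in adult hippocampus 10 of 10 in each case, with up to 4. In adult cortex it was 1 of 10 for VPA, 2 of 10 for running in MC, 10 of 10 for running in VPA and 1 of 10 for VPA with running. A split of the MC and MC+RW cortex arrays called 29 genes against a real 2, and a split for the hippocampal interaction 53 against 0. These were the highest of the other splits, whose median was 0 in both cases, and their cause was not tested. Where the real count was 0 every split matched it, which says nothing about chance: this holds for the 10 of 10 given above, for both interactions (100 of 100, the highest other 53 in hippocampus and 4 in cortex), the P84 genes (35 of 35, highest other 3) and the hippocampus and forebrain difference (100 of 100, highest other 20). Chance could not be excluded for the P84 lists (11 of 35 splits with 5 or more called, highest other 9) and the cohort difference (14 of 100, highest other 3).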

How the results depend on the processing

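The sex covariate and the persistence sets restricted to genes changed 2-fold or more were chosen only after the result was seen; the cause of each shift below was not tested. Signal over background limits every count, since dim probe sets sit at the floor. With every probe set the E14.5 counts became 10533 for VPA, 1934 for VPM and 10767 between them, and the cohort difference 2. With the values as deposited VPM at E14.5 gave 425. The E18.5 hippocampus then gave 60 for VPA, 9 for VPM and 58 between them, the forebrain 25, 4 and 21, and their difference 43. Adult cortex gave 2 for VPA, 1 for running in VPA and 2 for the interaction, and P84 10. Without a filter VPM at E14.5 gave 619, the E18.5 hippocampus 1 for VPA, 0 for VPM and 3 between them, and the forebrain 58, 2 and 7. Adult hippocampus gave 2 for VPA, 1 for running in MC, 2 for running in VPA, 1 for VPA with running and 3 for the interaction. Adult cortex gave 0 for VPA and 0 for VPA with running, P84 1 and the cohort difference 4, and 71 of 128 named genes kept their call. A filter at 200 gave 1 for running in MC and 2 for running in VPA in adult hippocampus and 7 for running in MC in cortex. Moderation without a trend gave 157 for VPA and 10 for VPA against VPM in the forebrain, and in cortex 0 for VPA, 0 for running in MC and 1 for VPA with running. Only the groups compared gave 2 for VPA against VPM in the E18.5 hippocampus, 153 for VPA, 1 for VPM and 19 between them in the forebrain, 1 for VPA in adult hippocampus, and 5 for VPA, 12 for running in MC and 5 for VPA with running in cortex. Quantile normalization gave 2 for VPA and 1 for running in MC in cortex. It also turned the camera direction of the glutamatergic synapse list of adult hippocampus with VPA, whose median became 0.0098, and of the ribosomal protein list of cortex with VPA (-0.011). The sex covariate gave 0 for VPM in the E18.5 hippocampus. With an estimated correlation 0 of 147 lists were called, while the genes higher at E14.5 passed in the forebrain (median 0.0207). Among genes changed 2-fold or more, the higher set had a median of 0.063 in the E18.5 hippocampus (adjusted p 0.00447, but unadjusted p 0.0737 with an estimated correlation), 0.065 in the forebrain (adjusted p 0.00172, unadjusted p 0.000237 with an estimated correlation), -0.00147 in adult hippocampus and -0.0116 in cortex. The lower set had -0.0293 in the forebrain (camera adjusted p 0.436) and -0.0499 in adult hippocampus (0.0938), and passed in neither.

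With the replicate number as a block, VPM in the forebrain gave 1, running in MC in cortex 1 and VPA with running in cortex 1. Pim3, Dclk1, Cdk18 and Gsk3b lost their calls in cortex, so the 1 call for running in MC was another gene, and Ccn3, Rprml, Sostdc1 and Prdm16 lost theirs between VPA and VPM in the forebrain. The labels give these samples only a number in common. In no set did every pair of same-numbered arrays correlate above 0.1, which cannot exclude a block. Pairs of the E18.5 forebrain ran from -0.281 to 0.376. In each E18.5 group replicate 3 had the lowest deposited trimmed mean. It was 229.8, 242.7 and 207.4 for MC, VPA and VPM in the hippocampus, and 240.1, 240 and 269.9 in the forebrain. The number may therefore mark a difference shared between groups, which was not tested further.

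Leaving out single arrays gave 5151 to 5421 for VPA, 531 to 977 for VPM and 5213 to 5541 between them at E14.5, with 738 and 768 for VPM without MC replicates 3 and 2. The E18.5 hippocampus gave 0 to 3, 0 to 1 and 0 to 4. The forebrain gave 36 to 172 for VPA (36 and 172 without VPA replicates 1 and 3, and 99, 69 and 66 without the MC arrays), 0 to 3 for VPM and 2 to 39 between them, with 4, 7 and 8 among the values. Adult hippocampus gave 0 to 4 for VPA, 0 to 7 for running in MC, 0 to 5 for running in VPA and 0 to 1 for the others. Cortex gave 0 to 4 for VPA, 0 to 128 for running in MC, 0 to 3 for running in VPA, 1 to 11 for VPA with running and 0 to 1 for the interaction. P84 gave 0 to 2, the tissue difference 0 to 1 and the cohort difference 1 to 9.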

Other observations

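The same-mouse test was chosen only after the result was seen, and its criterion was changed after that.

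Beyond the genes described, VPA at E14.5 raised Gadd45b (1.73), a stress gene tied to DNA demethylation, the heat shock gene Hspa2 (1.57) and the neurotrophin gene Bdnf (0.99, adjusted p 0.00115). It lowered Mfng (-1.15), which modifies Notch receptors, and Notch1 (-0.44). In the E18.5 forebrain Bdnf (-0.08, adjusted p 0.858) and Hspa2 (-0.06, 0.864) did not pass, while Mfng was still lower (-0.48, 0.0375).

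The immediate early genes of adult hippocampus and cortex deviated alike in arrays with the same number (r 0.963 over 12 deviations). In 13 reassignments of the numbers the correlation was as high, a share of 0.01 that became 0.123 adjusted over lists. Heat shock genes (r 0.891) and glucocorticoid targets (0.718) had smaller shares, both 0.0999 after adjustment, while the dentate granule neuron list gave r -0.665. Over all genes same-numbered adult arrays of the 2 tissues had a mean r of 0.0195, with 3 of 12 pairs over 0.1. Arrays from the same mouse and chance therefore cannot be told apart, since the list was picked for its likeness. The shares of Arc (0.00231), Sgk1 (0.00154), Fos (0.0201) and Dbp (0.0548) belong to genes picked after their values were seen. Genotypes or sample sheets of the adult mice would settle it, and a repeat of P84 immediate early genes with the handling time recorded would test whether handling, and not VPA, sets their level.

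A first hypothesis is that VPM moves the E14.5 telencephalon along its normal course, which the correlation of 0.615 with development allows but does not settle. It predicts that counts of somites or of S-phase cells in VPM and MC litters of the same hour differ, and it fails if these counts are alike while Eomes and Mcm4 still differ. A second hypothesis is that the fall of forebrain progenitor genes after VPA (0.365 with development) comes from progenitors used up early. It predicts fewer EOMES-positive cells per section at E18.5 in VPA, counted away from the choroid plexus, and it fails if their number equals that of MC. Any other loss of progenitors would lower the count too, so fewer cells would not single out this hypothesis. Immature neuron genes were also lower with VPA at E14.5 at the preset correlation, so no early gain of neurons was seen.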
